A study of Rattus norvegicus with 12 samples.

How the data were processed

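The data are RNA sequencing libraries of red gastrocnemius muscle from 6 male Wistar Kyoto rats aged 9 weeks, with 1 library of whole muscle and 1 of isolated mitochondria from each animal. Per the labels' protocols, mitochondria were isolated from fresh muscle by immunoprecipitation and treated with RNase A and proteinase K, RNA of both kinds was extracted on spin columns with a DNase I digest, and libraries were made with a kit that depletes ribosomal RNA, from 50 ng of muscle RNA and 10 ng of mitochondrial RNA. Groups came from the titles. Replicate numbers pair the groups, since muscle and mitochondria of a number carry the same animal number and the series text says that the mitochondria came from the corresponding muscle.

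The authors deposited 1 table of raw counts per gene, with a column per library and Ensembl gene identifiers and names, and no coordinates. The submitters' processing notes name FastQC 0.74, cutadapt 4.6, STAR 2.7.11a, HTSeq and the genome build mRatBN7.2; the strand setting, the treatment of reads that match several places and the annotation release are not given in the sources used here. All 12 columns mapped to a sample, and no row lacked a gene. Of 30560 genes, 24042 had a name and 660 had no count in any library. Mitochondrial genome genes were those with the name prefix Mt- or AY172581, 37 in all, of which 13 are named mRNAs and 24 are not named by function.

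Biotypes and chromosomes came from a RefSeq gene table of the assembly GRCr8, which is not the build of the counts, so that none of its coordinates are used: 17541 genes matched by symbol and 1576 by a synonym. A further 2072 were classed by a family name in the table, such as snoRNA or U6, and 9334 stayed unclassified. Nuclear noncoding genes were those with a known class other than protein coding, immunoglobulin, T cell receptor or pseudogene, 2552 in all, so that unclassified genes are not among them.

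CPM values are counts scaled to the total of gene counts in a library and are given as mean ± SD over 6 libraries. The muscle libraries held 24309444 to 32055355 counts and the mitochondria libraries 720111 to 1785865. Where a group had no count, a fold was computed against a floor of 3 counts over the group. Intervals for shares of 1 library are 95% Wilson intervals. Intervals and floors cover counting error only.

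Genes were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with TMM scaling over all genes, filterByExpr with a minimum count of 10, group as the only term and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. A positive log2 fold change means higher in mitochondria. A second fit took the mitochondrial genome alone, with the sum over its genes as library size. Shares of counts were compared with a two-sided exact permutation test over all groupings of 12 libraries into 6 and 6 (SciPy 1.17.1), whose smallest p is 0.0021645, and with a sign-flip test over 64 sign patterns for pairs, whose smallest p is 0.03125. The 25 gene lists were fixed before the data were examined, as were the tests, and were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, together with 6 biotype sets, 29 sets with members in all. Camera compares a list with all other genes tested.

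The genes named in the text follow a rule fixed before the data were examined, except those marked as picked out after their values were seen and those of the slope test in the closing observations. It takes every tested gene of the mitochondrial genome. It adds the 10 nuclear genes with the largest rise and the 10 with the largest fall that passed the threshold, had a mean CPM of at least 10 in the higher group and did not overlap between groups. It further takes the 10 noncoding genes with the largest rise and the 5 with the largest fall at a mean CPM of at least 1, the 3 most abundant members of each list with the one that changed most, and the 3 most abundant nuclear genes of the mitochondria libraries. Genes without a symbol were limited to 3 per direction. Part of the list members were left out for room.

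To check the pairing, the deviations of each library from its group mean were correlated over all tested genes between muscle and mitochondria of the same animal. The correlations lay between -0.0075 and 0.0201, and between -0.0147 and 0.0748 in the upper 25% of genes by level. A muscle library correlated best with its own mitochondria library in 2 of 6 animals over all genes and in 3 of 6 in the upper 25%. The reported tests had no animal term, and fits with the animal as a block are among the alternatives. These also comprise RLE size factors, total counts, the nuclear library alone, DESeq2 1.42.0, no filter, a fold size of at least 2, counts thinned to 573903 nuclear counts per library, each library left out in turn and, chosen after seeing the data, mitochondrial genome counts as library size, the fits without the 2 most abundant unnamed mitochondrial genes, the fit without mitochondria replicates 1 and 3 and shares of classes without the 5 noncoding genes most abundant in muscle.

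The methods were tested on simulated data with known answers. In counts simulated for the comparison of mitochondria with muscle over 26763 genes, edgeR recovered 52% of genes changed 2-fold and 92% of those changed 4-fold, and 2.70% of its calls were false. Only a small part of the genes was changed there, as many up as down, from a single profile shared by both groups. These rates therefore do not cover a comparison in which most genes are called, as in the data. For the fit of the mitochondrial genome alone (25 genes), both genes changed 4-fold and 1 of 2 genes changed 2-fold were recovered, and 25% of the calls were false. A slope test across the 6 mitochondria libraries, described in the closing observations, recovered 99.5% of 200 changed genes among 19429, with 4.78% false calls. Rank correlations between libraries had a median of 0.975 within muscle, 0.927 within mitochondria and 0.539 between the groups.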

Results

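Total RNA was sequenced from the red part of the gastrocnemius, a calf muscle rich in oxidative fibres, of male Wistar Kyoto rats aged 9 weeks. The 12 libraries fall into 2 groups of 6, which came from the same 6 animals. One group was made from whole muscle. The other was made from mitochondria that had been isolated from fresh tissue by immunoprecipitation and then treated with RNase A and proteinase K, enzymes that digest RNA and protein. Ribosomal RNA was depleted from both kinds of library, which started from 50 ng of RNA for muscle and 10 ng for mitochondria. The deposited table holds raw read counts for 30560 genes, of which 37 lie in the mitochondrial genome. The muscle libraries held 24309444 to 32055355 counts each and the mitochondria libraries 720111 to 1785865, so counting error weighs more on the mitochondria side. The study set out to find which RNAs are located in muscle mitochondria, with attention to noncoding RNAs encoded in the nucleus.

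The first question was how much of each library came from the mitochondrial genome. Its genes took 32.1% ± 4.30 of the counts in whole muscle (SD, n = 6) and 33.0% ± 14.8 in isolated mitochondria (SD, n = 6). The difference of 0.906 percentage points was smaller than the spread between replicates (two-sided exact permutation test, p = 0.883), and the share was higher in mitochondria in 3 of the 6 animals. The mitochondria libraries were far apart from each other: replicate 3 had 12.9% (95% Wilson interval 12.87 to 13.01) and replicate 4 had 51.5% (51.40 to 51.54), and the others had 20.3%, 28.9%, 41.2% and 43.4%. The 13 mRNAs of the mitochondrial genome, which encode subunits of the respiratory chain and of ATP synthase, made up 7.22% ± 1.02 of counts in muscle and 7.41% ± 2.69 in mitochondria (n = 6 each, exact permutation p = 0.892). Most of the remaining mitochondrial counts fell on AY172581.9 and AY172581.24, genes that carry no functional name in the table and together held 24.9% ± 3.86 of all muscle counts and 25.5% ± 12.2 of all counts in mitochondria. Leaving out single libraries moved the difference between -2.78 points, without mitochondria replicate 4, and 4.92 points, without mitochondria replicate 3, and it was also below 0 without mitochondria replicate 5 or 6 or muscle replicate 1 or 5.

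**Figure D1:**
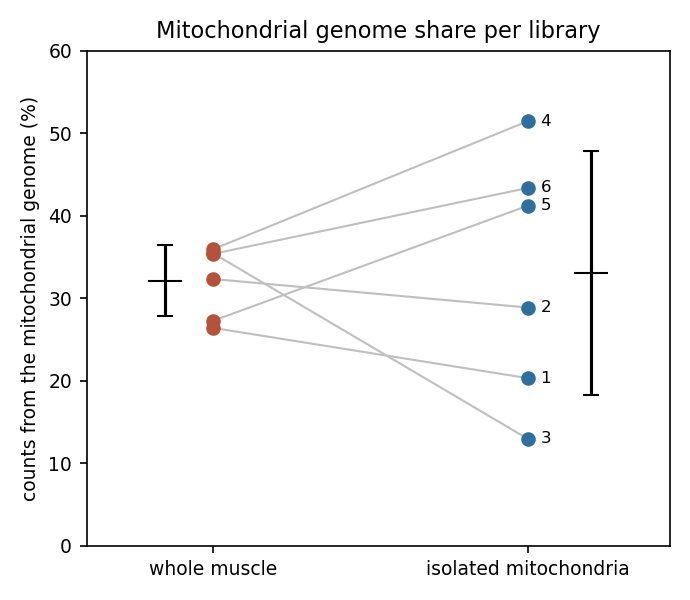
Percent of gene counts from the mitochondrial genome (vertical axis) in the 6 whole muscle and the 6 isolated mitochondria libraries. Each dot is a library, grey lines join libraries of the same animal (numbers give the replicate), and black bars show mean and SD. The muscle libraries lie between 26.4% and 35.9% and the mitochondria libraries between 12.9% and 51.5%.

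Within the transcripts of the mitochondrial genome, the proportions of several mRNAs shifted by small amounts and those of rare unnamed genes by large ones. Counted as a share of mitochondrial genome counts, Mt-nd5 rose from 1.34% ± 0.296 in muscle to 2.67% ± 0.744 in mitochondria, and Mt-nd1 from 1.03% ± 0.209 to 1.58% ± 0.341 (SD, n = 6 each). Both encode subunits of respiratory complex I. Mt-cyb, the cytochrome b of complex III, and Mt-nd2 rose by 0.42 on the log2 scale each, but passed no longer with TMM factors over the mitochondrial genes, at 0.10 and 0.14 (edgeR adjusted p = 0.484 and 0.338). Mt-co1, the catalytic subunit of complex IV, fell from 9.42% ± 0.925 to 7.60% ± 1.000, and Mt-atp6, a subunit of ATP synthase, from 2.07% ± 0.308 to 1.53% ± 0.232.

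In this fit, edgeR's quasi-likelihood test on the 25 mitochondrial genes with enough counts, 13 rose and 3 fell. The log2 differences were 0.99 ± 0.15 for Mt-nd5 (SE, edgeR adjusted p = 1.67e-10), 0.61 ± 0.17 for Mt-nd1 (edgeR adjusted p = 0.000590), -0.31 ± 0.09 for Mt-co1 (edgeR adjusted p = 0.00218) and -0.44 ± 0.15 for Mt-atp6 (edgeR adjusted p = 0.00617). The third gene that fell was AY172581.9, which went from 39.9% ± 2.52 to 36.4% ± 1.12 (edgeR adjusted p = 0.0363, and 0.213 in DESeq2), while AY172581.24 had 37.4% ± 1.05 and 39.5% ± 3.44 and did not pass the test. The 9 genes with the largest rise were AY172581.20, AY172581.7, AY172581.18, AY172581.19, AY172581.21, AY172581.8, AY172581.22, AY172581.6 and AY172581.2, with log2 differences from 3.49 (AY172581.2) to 8.51 (AY172581.20). They were rare: AY172581.21, the most abundant of them in mitochondria, had 355 ± 70.7 CPM (counts scaled to the library total) there and 10.9 ± 2.89 in muscle, where AY172581.2 had the most, with 22.2 ± 3.28. Mt-atp8, Mt-nd4l, Mt-nd4, Mt-nd3, Mt-co3, Mt-co2, Mt-nd6 and AY172581.15 did not pass, with log2 differences from -0.72 for Mt-atp8 to 0.87 for AY172581.15. Of these, Mt-atp8 fell in DESeq2 (DESeq2 adjusted p = 0.0398) and with TMM factors over the mitochondrial genes (edgeR adjusted p = 0.00220). Mt-nd4l and Mt-nd4 also fell with those factors, at -0.45 and -0.37 on the log2 scale (edgeR adjusted p = 0.0119 and 0.0117). With TMM factors over the mitochondrial genes, 11 rose and 6 fell, with 0.31 for Mt-nd1 and -0.62 for Mt-co1, and 2 to 4 genes fell when single libraries were left out. Reads from neighbouring genes on opposite strands cannot be separated here, because the strand setting of the counting is not given in the sources used here.

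**Figure D2:**
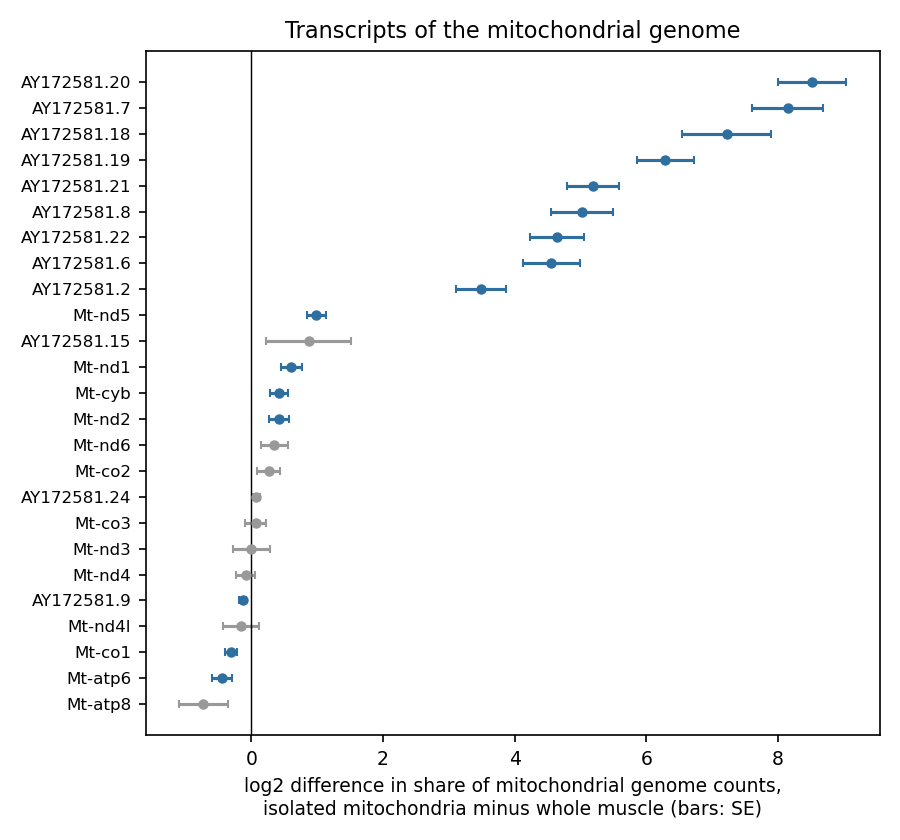
Log2 difference in the share of mitochondrial genome counts between isolated mitochondria and whole muscle (horizontal axis) for the 25 genes tested, with SE bars from edgeR and n = 6 libraries per group. Blue marks genes with an adjusted p under 0.05. The 9 genes at the top lie between 3.49 and 8.51, and the named mRNAs lie between -0.72 and 0.99.

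The second question was which genes, nuclear ones above all, were higher or lower in the mitochondria libraries. Several mRNAs that dominate skeletal muscle were among the genes that fell furthest. Acta1, the actin of skeletal muscle, had 23812 ± 3674 CPM in muscle and 43.5 ± 6.09 in mitochondria (SD, n = 6 each), Myh4, a fast myosin heavy chain, had 36677 ± 12731 and 211 ± 55.3, and Ckm, the creatine kinase of muscle, had 9452 ± 2244 and 34.2 ± 4.51. Among the genes that rose, Muc5b, a mucin of the airways, and Loxhd1 and Tecta, genes of the inner ear, had no count in any muscle library and 156 ± 34.9, 130 ± 42.7 and 86.2 ± 22.4 CPM in mitochondria. Nuclear subunits of the respiratory chain fell with the sarcomere genes, although by less. Other mitochondrial lists, such as mitochondrial ribosomal proteins, fell with TMM scaling and went both ways with total counts.

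The test was edgeR's quasi-likelihood test with TMM scaling on 24679 genes. It called 15544 genes higher and 7470 lower in mitochondria, and 67.5% of the called genes were higher. With any single muscle library left out, 20003 to 20007 genes passed the filter for low counts and 11478 to 11556 were higher. The split also depends on the scaling. With total counts as the only scaling, which moves the median log2 fold change by 2.10, it was 20795 higher and 2228 lower (90.3% higher), and relative to mitochondrial genome counts, a scaling chosen after seeing the data, 19614 nuclear genes were higher and 1071 lower (94.8% higher). The median over all genes tested was 2.51 with TMM, 4.61 with total counts and, over nuclear genes, 4.81 relative to mitochondrial genome counts. A gene with a log2 fold change of 0 thus lies far below the middle of the genes, and a rise below these medians is smaller than that of the middle gene. The TMM median depends on the filter for low counts, and was 1.18 to 1.21 with any single muscle library left out. After thinning all libraries to 573903 nuclear counts, 8402 genes were higher and 4085 lower among 14440 tested.

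The 10 nuclear genes with the largest fall were AABR07039058.1, Acta1, a copy of Ndufs5 (ENSRNOG00000029339), Mylpf, Ckm, AABR07005775.1, Myl1, Myh4, Tnnc2 and Tnni2. Mylpf and Myl1 are myosin light chains and Tnnc2 and Tnni2 are troponins of fast fibres. Their log2 fold changes were -11.17 ± 0.36 for Acta1 (SE, edgeR adjusted p = 1.19e-22), -10.83 ± 0.30 for Mylpf, -10.19 ± 0.30 for Ckm, -9.69 ± 0.30 for AABR07005775.1, -9.62 ± 0.26 for Myl1, -9.57 ± 0.40 for Myh4, -9.55 ± 0.28 for Tnnc2 and -9.36 ± 0.24 for Tnni2. AABR07039058.1 (3125 counts in muscle) and the Ndufs5 copy (2702 counts in muscle) had no count in mitochondria, so by CPM they were at least 47.9-fold and at least 41.4-fold lower, with the floor set at 3 counts over the group. A second gene named Ndufs5 had 4622 counts in muscle and 65 in mitochondria, and counts can be split between such near-identical copies. Ttn, the giant protein titin, fell by 7.61 on the log2 scale but remained the third most abundant nuclear gene of the mitochondria libraries, at 1742 ± 679 CPM.

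With genes that lack a symbol limited to 3, the 10 nuclear genes with the largest rise were ENSRNOG00000070738, ENSRNOG00000068779, ENSRNOG00000046714, Muc5b, Loxhd1, Fat2, AABR07069821.1, Sult1c2a, Tecta and Pkd1l3. Fat2 encodes an atypical cadherin and Sult1c2a a sulfotransferase. Of these, 7 had no muscle count, and against the floor of 3 counts over the group they were at least 18797-fold (ENSRNOG00000070738), 8438-fold (Muc5b), 6821-fold (Loxhd1), 6205-fold (Fat2), 5857-fold (AABR07069821.1), 4610-fold (Tecta) and 4291-fold (Pkd1l3) higher by CPM. Sult1c2a had 2 counts in muscle and 2077 in mitochondria, a ratio of 22584 by CPM (95% exact interval 6244 to 186609, counting error only). The ratio was 75244 (13496 to 2972840) for ENSRNOG00000068779 and 46832 (12957 to 386831) for ENSRNOG00000046714. The largest adjusted p of the 10 was 8.91e-22, for Tecta (edgeR's quasi-likelihood test). The most abundant nuclear genes of the mitochondria libraries were ENSRNOG00000067240 (4325 ± 841 CPM, against 0.406 ± 0.222 in muscle) and ENSRNOG00000064423 (2209 ± 483, against 0.120 ± 0.106).

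The rise spread over most of the nuclear genome. The mitochondria libraries had counts for 28325 ± 313 genes and the deeper muscle libraries for 17395 ± 284 (SD, n = 6 each). The exact permutation test, which ignores the pairing, gave p = 0.0021645, and the paired sign-flip test gave p = 0.03125, each the smallest that test can give. Thinned to 573903 nuclear counts each, they had counts for 27713 ± 71.0 and 12452 ± 121 nuclear genes. Of 10014 nuclear genes without any muscle count, 93.4% had a count in mitochondria and 64.6% had one in all 6 mitochondria libraries. Olfactory receptors, best known from the nose, had 11.2 ± 1.46 CPM of nuclear counts in muscle and 13825 ± 500 in mitochondria, and vomeronasal type 1 receptors 0.0842 ± 0.0906 and 1283 ± 52.2 (exact permutation adjusted p = 0.0021645 for each, n = 6). The 10 nuclear genes most abundant in muscle took 30.5% ± 2.74 of nuclear counts there and 0.416% ± 0.106 in mitochondria. Across coding genes grouped by their muscle level, the median in mitochondria went from 13.8 CPM of nuclear counts, for genes silent in muscle, to 81.0, for genes above 1000 in muscle, whose muscle median was 2241. Genes without a name took 1.46% ± 0.251 of nuclear counts in muscle and 12.9% ± 0.254 in mitochondria.

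**Figure D3:**
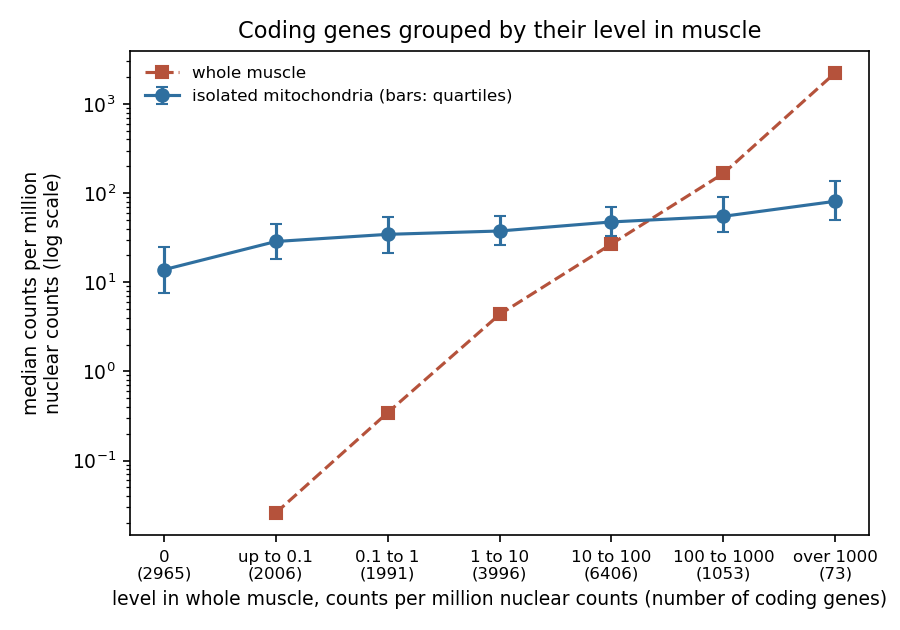
Median CPM of nuclear counts (vertical axis, log scale) of coding genes grouped by their level in whole muscle (horizontal axis, number of genes in brackets), in whole muscle and in isolated mitochondria, with quartiles over genes for the latter and counts summed over the 6 libraries of a group. The muscle median of the first group is 0 and is not drawn. The median in mitochondria goes from 13.8 to 81.0 while that in muscle goes up to 2241.

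The genes of the contractile apparatus fell as a group. All 37 members of the sarcomere list that were tested fell, with a median log2 fold change of -7.62 under TMM and -5.48 with total counts, where 36 fell (camera adjusted p = 1.29e-21). Of the 20 genes of glycolysis and glycogen breakdown, 18 fell (median -5.36, and -3.26 with total counts, camera adjusted p = 1.25e-10), among them the glycogen phosphorylase Pygm (from 3850 ± 1066 to 50.3 ± 12.8 CPM), Gapdh (from 2592 ± 795 to 45.7 ± 13.2) and the enolase Eno3 (from 2499 ± 558 to 39.5 ± 15.3). Hk1 and a copy of Aldoa (ENSRNOG00000067655), picked out after their values were seen, rose by 0.29 and 2.05 on the log2 scale (for Hk1, 2.41 with total counts). Of 81 cytosolic ribosomal protein genes 75 fell and 6 rose (median -3.98; 68 and 7 with total counts, median -1.91; camera adjusted p = 2.82e-23). Rplp0 went from 280 ± 10.8 to 19 ± 4.01 CPM and Rpl4 from 214 ± 26.8 to 12.7 ± 5.52.

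Lists of nuclear genes with mitochondrial products fell under TMM to differing degrees. Of 77 nuclear subunits of the respiratory chain and ATP synthase, 72 fell (median -5.55, and -3.48 with total counts, where 70 fell; camera adjusted p = 1.89e-25). Atp5f1b, the catalytic subunit of ATP synthase, went from 1884 ± 25.2 to 17.9 ± 6.59 CPM (log2 fold change -8.89 ± 0.20, SE, edgeR adjusted p = 7.26e-26), Atp5f1a from 1614 ± 172 to 31.8 ± 7.0 and Sdha, of complex II, from 616 ± 51.3 to 36.3 ± 10.0. Another 5 rose. Among these, singled out after their values were seen, were genes with few counts in muscle: Cox7a1 (3.21 ± 0.599 CPM in muscle, 30 ± 11.2 in mitochondria), Ndufs6 (0.0688 ± 0.0571 and 6.33 ± 1.89), a copy of Atp5mc1 (ENSRNOG00000007235, none and 11.5 ± 5.40) and a copy of Ndufb2 (ENSRNOG00000026616, none and 6.48 ± 3.56). Of 36 genes of the citric acid cycle and fatty acid oxidation 35 fell (median -5.13, and -3.02 with total counts, where 34 fell; camera adjusted p = 4.44e-19), among them Ogdh (from 695 ± 61.3 to 55.6 ± 19 CPM) and Idh2 (576 ± 75.7 to 41.7 ± 9.29). All 27 genes of mitochondrial dynamics and antioxidant defence fell (median -3.88; with total counts 22 fell and 3 rose, median -1.79; camera adjusted p = 1.05e-14), such as the fusion protein Mfn2 (235 ± 20.5 to 55.1 ± 10.6), the kinase Pink1 (422 ± 11.2 to 36.9 ± 5.6) and the superoxide dismutase Sod2 (266 ± 30.1 to 21.2 ± 7.60).

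Of 34 protein import genes 32 fell (median -2.83, camera adjusted p = 6.03e-14). With total counts 20 fell and 8 rose (median -0.75), and relative to mitochondrial genome counts 10 fell and 5 rose (median -0.36). They included the chaperone Hspa9 (249 ± 24.0 to 35.0 ± 11 CPM), Samm50 of the outer membrane (120 ± 14.3 to 39.6 ± 15.2) and Timm23 of the inner membrane (112 ± 12.3 to 14.9 ± 4.81). Of 72 mitochondrial ribosomal protein genes 69 fell (camera adjusted p = 6.55e-20), with a median of -2.25 under TMM, -0.16 with total counts and 0.19 relative to mitochondrial genome counts. With total counts 26 fell and 16 rose, and relative to mitochondrial genome counts 7 fell and 12 rose. Mrpl12 went from 84.4 ± 4.05 to 19.3 ± 5.21 CPM, Mrpl54 from 82.8 ± 11.6 to 8.28 ± 3.48 and Mrps15 from 61.1 ± 8.70 to 30.1 ± 10.8 (relative to mitochondrial genome counts -0.69, edgeR adjusted p = 0.192). Mrps17 and a copy of Mrpl42 (ENSRNOG00000025964), picked out after their values were seen, rose by 2.26 and 4.25 on the log2 scale. Of 23 carriers and channels of the mitochondrial membranes 18 fell (camera adjusted p = 2.76e-07), with medians of -2.22, -0.14 and 0.17 under those scalings, and 11 fell and 9 rose with total counts. They included the adenine nucleotide carrier Slc25a4 (2364 ± 174 to 18.6 ± 4.42 CPM), the channel Vdac1 (644 ± 116 to 52.9 ± 12.9) and Slc25a12 (326 ± 13.4 to 38.7 ± 6.33). Slc25a10, Slc25a1 and Slc25a13, likewise picked out after their values were seen, rose by 1.52, 0.93 and 2.23. Of 35 genes of the machinery that expresses the mitochondrial genome 28 fell (camera adjusted p = 1.76e-09) and Polg2 and Mterf2, also picked out after their values were seen, rose by 1.44 and 0.63. The median was -1.34 under TMM, 0.74 with total counts, where 23 rose and 7 fell, and 1.13 relative to mitochondrial genome counts, where 16 rose and 2 fell. These medians lie below those over all genes tested, which were 2.51, 4.61 and 4.81 under the same scalings. Camera compares a list with the other genes tested, and with total counts it still placed this expression list lower (camera adjusted p = 2.72e-05). The camera results thus put a list below the other genes and do not by themselves show a fall. Medians of coding genes varied far less in mitochondria than in muscle, so how far a list fell also follows its level in muscle. The 13 mRNAs of the mitochondrial genome all fell under TMM (median -1.92), whereas their median was 0.06 with total counts, where 2 rose (Mt-nd1 and Mt-nd5) and 1 fell (Mt-atp8). Their camera adjusted p was 0.000111, and adjusted p = 0.339 with an estimated correlation.

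Markers of other cell types of muscle went different ways, and the medians for endothelium, smooth muscle and Schwann cells changed sign with the scaling. Of 14 endothelial markers all 14 fell under TMM (median -2.25, camera adjusted p = 4.47e-08), as did 11 of 12 markers of smooth muscle and pericytes (median -2.31, camera adjusted p = 3.32e-06), but relative to mitochondrial genome counts those medians were 0.17 and 0.19. Under that scaling 3 endothelial markers fell and none rose, and 1 marker of smooth muscle and pericytes fell and 1 rose. With total counts 6 endothelial markers fell and 1 rose (median -0.15), and 5 of the others fell and 2 rose (median -0.20). Aqp1, a water channel of capillaries, went from 189 ± 38.4 to 27.7 ± 11.4 CPM, Cdh5 from 137 ± 30.2 to 40.2 ± 14.8 and Rgs5 from 111 ± 22.5 to 16.6 ± 5.31. Cnn1, picked out after its value was seen, rose by 1.53 on the log2 scale. Vwf had 102 ± 20.6 and 140 ± 32.8 and Myh11 143 ± 23.8 and 124 ± 31.4. Vwf fell under TMM (-1.69) and rose with total counts (0.44), and Myh11 fell under TMM (-2.34) and had 0.20 relative to mitochondrial genome counts. Of 18 fibroblast and matrix genes 17 fell (median -3.01, camera adjusted p = 3.39e-08; adjusted p = 0.0966 with an estimated correlation). With total counts 11 fell and 3 rose (median -0.89), and relative to mitochondrial genome counts 7 fell and 3 rose (median -0.49). They included Col3a1 (1220 ± 264 to 87.6 ± 9.73), Sparc (634 ± 225 to 45.0 ± 5.84) and Col1a1 (1166 ± 1177 to 126 ± 20.4), whose muscle value was 3558 in replicate 6 and at most 880 in the others.

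Of 24 macrophage and leukocyte markers 11 rose and 7 fell under TMM (median 0.47). Of the 24, 22 rose and 1 fell with total counts (median 2.53), and 22 rose and none fell relative to mitochondrial genome counts (median 2.74). With total counts, however, 20795 of all 24679 genes tested rose. The median over all genes tested, 4.61, lies above the total-count median of each list in this paragraph. Ptprc, the pan-leukocyte marker, went from 7.53 ± 1.2 to 80.2 ± 23.5 CPM. Csf1r had 15.9 ± 3.56 and 78.8 ± 14.3 (log2 fold change 0.20 ± 0.13, SE, edgeR adjusted p = 0.135; 2.29 with total counts, edgeR adjusted p = 5.81e-21). The platelet gene Ppbp had no muscle count and 6.17 ± 1.83. Of 13 adipocyte genes 8 rose and 2 fell under TMM (median 0.89), and 11 and 2 with total counts (median 2.97). Lpl went from 301 ± 106 to 30.2 ± 3.06 and Plin4 from 193 ± 28.2 to 41.9 ± 12.6. Fasn had 23.9 ± 8.27 and 110 ± 29.1 (log2 fold change 0.05, edgeR adjusted p = 0.775; 2.18 with total counts, edgeR adjusted p = 2.26e-18). Ucp1, the uncoupling protein of brown fat, had no muscle count and 12.1 ± 5.91. Of 10 red blood cell genes 6 rose and 4 fell under TMM (median 2.27), and 7 and 3 with total counts (median 4.36). Hba-a2 and Hbb-b1, the globins, went from 58.9 ± 27.4 to 28.8 ± 14.3 and from 64.3 ± 20.7 to 11 ± 3.0 (for Hba-a2, -0.55 relative to mitochondrial genome counts, edgeR adjusted p = 0.298). Of 10 Schwann cell genes 3 rose, among them Mag (0.425 ± 0.265 to 38.8 ± 10.8), and 4 fell under TMM (median -0.04). With total counts 8 rose and 2 fell (median 2.06). Of 10 genes in the satellite cell list 4 rose and 5 fell under TMM (median 0.13), led by Des (1934 ± 263 to 35.8 ± 9.25), which mature fibres also express. With total counts 8 rose and 2 fell (median 2.25). None of these 5 lists passed camera, with adjusted p of 0.646, 0.920, 0.635, 0.228 and 0.266 in the order given. Over all 23 lists with members, counts of genes adjusted over the list alone equalled those adjusted over all genes tested, and of the 16 lists that passed camera all but 4 also passed with an estimated correlation.

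**Figure D4:**
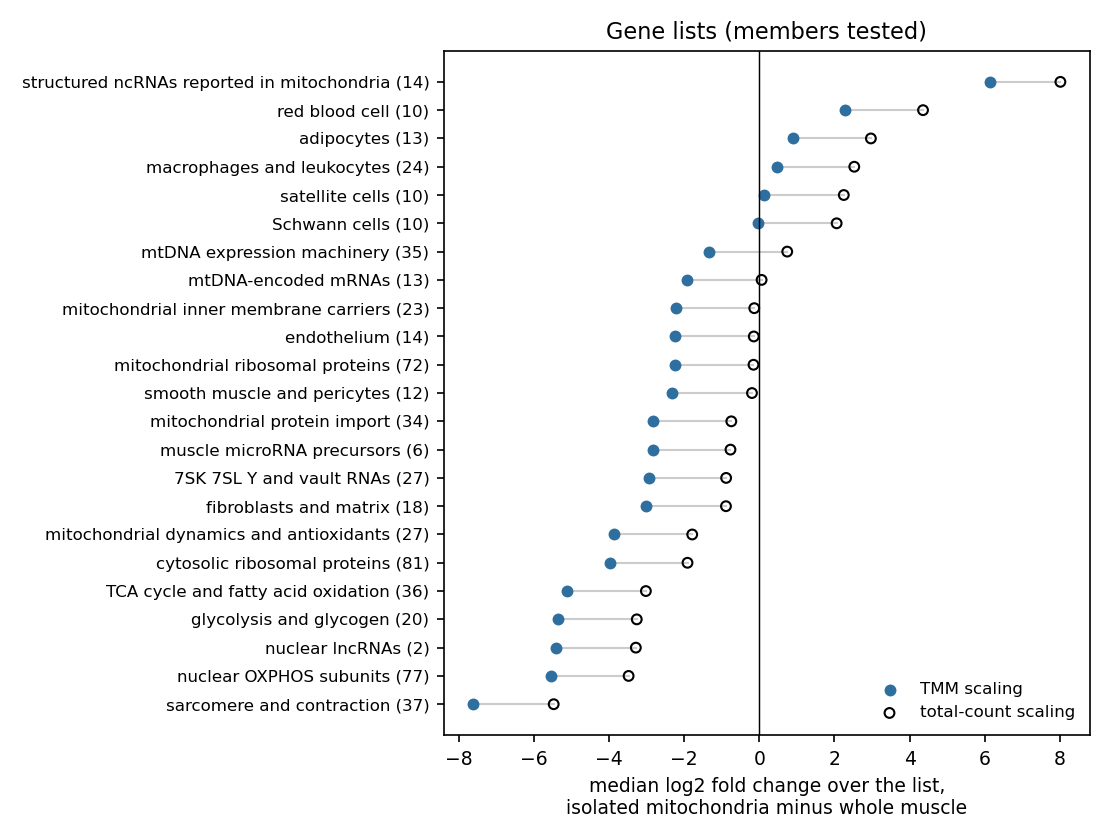
Median log2 fold change (horizontal axis, isolated mitochondria minus whole muscle, n = 6 libraries per group) of each gene list with members tested, under TMM (filled) and total-count scaling (open). The number of members tested stands in brackets. The sarcomere list lies lowest at -7.62, and the total-count medians lie about 2 log2 units higher than those under TMM, which moves the mitochondrial genome mRNAs from -1.92 to 0.06 and the mitochondrial genome expression list from -1.34 to 0.74.

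The third question was which nuclear noncoding RNAs were in the mitochondria libraries. The abundant noncoding RNAs of muscle fell: the imprinted long noncoding RNA H19 went from 1925 ± 400 to 22.1 ± 9.70 CPM, Rpph1, the RNA of RNase P, from 2770 ± 940 to 30.9 ± 17.5, and RNase_MRP, the RNA of the related endonuclease that has been reported in mitochondria, from 485 ± 67.4 to 50.7 ± 36.5 (SD, n = 6 each). The genes that rose had few or no counts in muscle. Such rises were not particular to noncoding genes: of all 10014 nuclear genes without any muscle count, 93.4% had a count in mitochondria. The rises therefore do not show that these RNAs lie inside mitochondria. The long noncoding RNA Fendrr rose from 0.0228 ± 0.0275 to 67.2 ± 13.1 CPM, and Ceacam6, Asip, Krbox1, the microRNA precursor Mir129-2, a copy of RNaseP_nuc (ENSRNOG00000054444) and a copy of 5.8S rRNA (ENSRNOG00000067463) had no muscle count and between 5.58 ± 1.58 (Mir129-2) and 24.0 ± 6.10 (Ceacam6) in mitochondria. Over all 2552 noncoding genes, their share of nuclear counts was 0.946% ± 0.178 in muscle and 0.474% ± 0.0338 in mitochondria (exact permutation adjusted p = 0.00231, lower in mitochondria in 6 of 6 animals). This fall was that of the 5 most abundant in muscle, H19, Rpph1, RNase_MRP and 2 copies of 7SL RNA, which went from 0.878% ± 0.168 to 0.0215% ± 0.0104: without them, a choice made after seeing the data, the share rose from 0.0678% ± 0.0136 to 0.453% ± 0.0278 (exact permutation adjusted p = 0.00232).

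Of 232 nuclear noncoding genes tested by edgeR's quasi-likelihood test, 171 were higher and 45 lower. The log2 fold changes were -8.67 ± 0.23 for H19 (SE, edgeR adjusted p = 1.57e-24), -8.51 ± 0.32 for Rpph1 (edgeR adjusted p = 4.51e-21), -5.28 ± 0.30 for RNase_MRP (edgeR adjusted p = 1.48e-16) and 8.97 ± 0.28 for Fendrr (edgeR adjusted p = 6.24e-23). Copies of 7SL RNA, the RNA of the signal recognition particle, had -6.51 (Metazoa_SRP, ENSRNOG00000048993) and -6.27 (Metazoa_SRP, ENSRNOG00000055825), and a Y_RNA copy (ENSRNOG00000060430) had -6.28. Against the floor of 3 counts over the muscle group, Ceacam6 was at least 1312-fold, Asip at least 573-fold, the 5.8S copy at least 515-fold, Krbox1 at least 377-fold, the RNaseP_nuc copy at least 348-fold and Mir129-2 at least 326-fold higher. Ceacam6, Asip and Krbox1 are classed as noncoding only by the annotation used for biotypes, RefSeq on the assembly GRCr8. The count of higher genes rests on the filter for low counts: leaving out any single muscle library left 30 or 31 noncoding genes tested and 9 higher, thinning left 16 tested and 5 higher, and with no filter 1829 were higher.

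By class, the shares of nuclear counts went both ways. Rises from very low levels were also seen in families of coding genes, such as olfactory receptors, and are not particular to noncoding classes. Long noncoding RNAs fell from 0.287% ± 0.0420 in muscle to 0.0326% ± 0.00192 in mitochondria through H19 alone, and the other 15 rose together from 0.00506% ± 0.000674 to 0.0294% ± 0.00200, a split made after seeing the data. Falls were also seen in signal recognition particle RNAs, from 0.136% ± 0.0537 to 0.0180% ± 0.00341, and in Rpph1 with RNase_MRP, from 0.486% ± 0.168 to 0.0128% ± 0.00887. Small nuclear RNAs rose from 0.00342% ± 0.000586 to 0.230% ± 0.0180, microRNA precursors from 0.00632% ± 0.000900 to 0.0768% ± 0.00430, small nucleolar RNAs from 0.00712% ± 0.00120 to 0.0475% ± 0.00299 and nuclear ribosomal RNA genes from 0.00218% ± 0.00105 to 0.0299% ± 0.00741. Each of these classes had an exact permutation adjusted p of 0.00231 over 16 classes, near the smallest this unpaired test can give. The paired sign-flip test gave an adjusted p of 0.0333 for each, and each moved the same way in 6 of 6 animals. Y RNAs, at 0.00371% ± 0.00167 and 0.00388% ± 0.00140, did not differ (exact permutation p = 0.846).

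The lists of noncoding RNAs fixed beforehand were mixed. Of 14 genes in the list of structured RNAs reported in mitochondria 12 rose, all of them copies of 5S rRNA or RNaseP_nuc with at most 48 counts in mitochondria, and 2 fell, Rpph1 and RNase_MRP (median 6.15, or 5.12 with genes without muscle counts set at their floor; camera adjusted p = 0.413). Of 27 copies of 7SK, 7SL, Y and vault RNAs 9 rose and 17 fell (median -2.93; with total counts 11 rose and 14 fell, median -0.88; camera adjusted p = 0.00109; adjusted p = 0.0758 with an estimated correlation). In the list of long noncoding RNAs, which had 2 members tested, H19 and a copy of Tug1 (ENSRNOG00000064262) fell (camera adjusted p = 0.0434; adjusted p = 0.124 with an estimated correlation). Tug1 had 5.91 ± 0.973 and 6.15 ± 3.48 CPM and a log2 value of -0.04 with total counts and 0.34 relative to mitochondrial genome counts. Of 6 muscle microRNA precursors 4 fell and Mir146a, picked out after its value was seen, rose by 2.14 (median -2.84; with total counts 3 fell and 2 rose, median -0.77; camera adjusted p = 0.0617, and 0.0450 with the animal as a block). Mir1b went from 8.75 ± 5.27 to 3.06 ± 2.21, Mir133b from 5.65 ± 3.88 to 1.92 ± 0.603 (relative to mitochondrial genome counts -1.49, edgeR adjusted p = 0.0640) and Mir22 from 3.85 ± 1.11 to 1.24 ± 0.724 CPM. Copies of these small RNA genes share sequence, so counts of single copies are uncertain, and no gene of the table is named as a ribosomal or transfer RNA of the mitochondrial genome, so the lists of those RNAs had no members.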

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

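No test in this part was chosen after seeing a result, but some of the genes searched were named only after their values or slopes were seen. In groups of 6 libraries, the values of the genes named in the text were searched for a single library that stood far from the other 5 by Dixon's test, and 22 of 264 groups of values held one. Chance flags about 1 in 20 such groups, so many of the libraries listed here may be no more than that. All values are CPM, with the range of the other 5 libraries in brackets.

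Mitochondria replicate 3, the library with the lowest share of mitochondrial genome counts, was high for Aqp1 at 49.5 (15.7 to 25.9), Cdh5 at 69.8 (28.6 to 37.5), Myh11 at 184 (98.6 to 128), Ptprc at 125 (55.9 to 80.2), and the copies of Ndufb2 (ENSRNOG00000026616) at 13.5 (4.17 to 6.74) and Mrpl42 (ENSRNOG00000025964) at 7.88 (2.03 to 4.17). Mitochondria replicate 1 was high for AY172581.6 at 165 (56.3 to 95.03). Muscle replicate 6 was high for the matrix genes Col1a1 at 3558 (559 to 880) and Sparc at 1068 (447 to 611), for a 7SL RNA copy (Metazoa_SRP, ENSRNOG00000048993) at 746 (245 to 422), and for Coch at 0.370 (0 in all others) and ENSRNOG00000070284 at 0.111 (0 to 0.0376), both with few reads.

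Muscle replicate 1 was high for Tnnc2 at 8381 (3739 to 5345), AY172581.22 at 13.1 (6.77 to 8.44) and AY172581.18 at 0.133 (0 to 0.0411). Muscle replicate 4 was high for AY172581.8 at 4.44 (0.732 to 1.68) and for ENSRNOG00000068307 at 5352 (1009 to 2507). Muscle replicate 2 was high for Sod2 at 325 (247 to 269) and held the only muscle counts of Sult1c2a, at 0.0650 (0 in all others). Muscle replicate 3 was high for Hk1 at 23.6 (15.1 to 18.1) and held the only muscle count of ENSRNOG00000068779, at 0.0312 (0 in all others). Muscle replicate 5 was high for Polg2 at 2.78 (1.37 to 1.76).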

How the results depend on the processing

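The scaling to mitochondrial genome counts, the fits without the 2 most abundant unnamed mitochondrial genes, the fit without mitochondria replicates 1 and 3 and the shares without 5 noncoding genes were chosen after seeing the data. The alternative without nuclear copies of the mitochondrial genome was not run, because no genome sequence was given, and mitochondrial rRNAs could not be left out by name, because none is named. The shift within the mitochondrial genome covered 16 genes, and 15 to 19 under the alternatives. With the animal as a block, 15511 genes were higher and 7427 lower, and apart from the microRNA list given above and the adipocyte list below, which did not pass either way, the block changed no other call of a list or a named gene.

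Thinned counts gave 8402 higher and 4085 lower genes, and 8357 and 4049 with the animal as a block. Of 7454 nuclear genes that fell, 6605 were tested again and 4085 fell again; their log2 values moved up by a median of 1.03, and of the 2520 lost calls 1618 had been above -1.03. Among noncoding genes they gave 5 higher and 10 lower, with the block 5 and 10. Total counts gave 2228 lower genes and 26 lower noncoding genes, and mitochondrial genome counts as library size 1071 and 23, since these scalings raise all log2 fold changes. Higher noncoding genes numbered 1645 with DESeq2 and 1829 with no filter, which test more genes, and 266 without mitochondria replicates 1 and 3. With single libraries left out they numbered 9 to 305, and the lower ones 19 to 52, because the filter for low counts moves with the median library size. The difference in mitochondrial share ranged from -2.78 to 4.92 points with single libraries left out.

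Total counts turned the sign of these log2 values: Mt-nd3 0.0442, Mt-co3 0.0606, AY172581.24 0.16, Mt-co2 0.26, Mt-nd6 0.36, Mt-cyb 0.38, Mt-nd2 0.40, Mt-nd1 0.58, Mt-nd5 0.91, AY172581.15 0.99, Vwf 0.44, ENSRNOG00000062337 0.28, ENSRNOG00000064743 0.98 and 5_8S_rRNA (ENSRNOG00000070263) 1.73. Mitochondrial genome counts did so for Tug1 (ENSRNOG00000064262) 0.34, Vwf 0.84, Myh11 0.20, ENSRNOG00000062337 0.14, ENSRNOG00000064743 0.97 and the 5_8S_rRNA copy 1.69. That copy also turned with DESeq2 (0.0757), RLE factors (0.10) and thinned counts (0.56), and Fasn had -0.0110 with no filter. RLE factors moved the median log2 value over all genes tested up by 0.37. The cause of the turns with DESeq2, thinned counts and no filter was not tested. The direction of list tests that did not pass turned for structured RNAs (camera adjusted p = 0.746) and macrophages and leukocytes (camera adjusted p = 0.970) with total counts and for adipocytes with the animal as a block (camera adjusted p = 0.995). The cause was not tested.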

Other observations

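In this part, the tests of carry-over, of RNA held inside mitochondria and of shared reads and the folds after thinning were chosen after seeing the results. So were the chromosome X ratios other than that for genes without muscle counts. All other tests were chosen before. Further gene families rose together in the mitochondria libraries, as CPM of nuclear counts (SD, n = 6 each). Vomeronasal type 2 receptors went from 0.401 ± 0.284 to 1673 ± 77.4, bitter taste receptors from 0.365 ± 0.282 to 236 ± 15.3, keratin-associated proteins of hair from 0.0151 ± 0.0369 to 216 ± 12.7 and beta defensins from 0.0558 ± 0.0626 to 200 ± 10.3. The 796 copies of U6 small nuclear RNA went from 10.96 ± 1.38 to 1172 ± 134 (exact permutation adjusted p = 0.0021645 for each family).

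The counts on nuclear genes without any muscle count could come from residual nuclear DNA, from cytosolic RNA of muscle or from RNA held inside mitochondria. If they came from DNA, receptor genes of like length should have like counts, and the ratio of the median for vomeronasal type 1 to that for olfactory receptors was 1.43 (95% bootstrap interval 1.09 to 1.84), while that of bitter taste to olfactory receptors was 0.689 (0.633 to 0.864), so these medians were alike only within a factor of about 2. In male animals chromosome X should have 0.5 times the counts of autosomes, and the ratio was 0.458 (0.375 to 0.571; 93 and 2863 coding genes placed by the assembly GRCr8, gene length not controlled), or 0.283 (0.271 to 0.696) for 4 olfactory receptors on X and 0.414 (0.351 to 0.494), below 0.5, for coding genes with up to 1 CPM of nuclear counts in muscle, so the ratios are consistent with residual DNA, in spite of a DNase step, in direction more than in exact size. Carry-over of cytosolic RNA should keep the 10 genes most abundant in muscle abundant, but their share of nuclear counts was at most 0.568% in any mitochondria library, against 30.5% in muscle, which excludes it as the whole source. RNA held inside mitochondria is also part of muscle and might be expected to keep its ratio to mitochondrial genome counts. For olfactory, vomeronasal type 1 and bitter taste receptors the lowest mitochondria library lay above the highest muscle library by a factor of 459, 1802 and 114. For genes without muscle counts chosen in 3 animals and measured in the other 3 (20 choices), the factor was 1123 or more. However, rare genes of the mitochondrial genome itself did not keep that ratio either, with rises of up to 8.51 on the log2 scale (AY172581.20). The test therefore cannot exclude RNA held inside mitochondria.

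Across the 6 mitochondria libraries, 5 of 19760 nuclear genes rose with the ratio of mitochondrial to nuclear counts with a slope above 0.5, or 2 to 6 with single libraries left out: ENSRNOG00000068307 (slope 0.82), a copy of 5.8S rRNA (ENSRNOG00000070263, 0.80), ENSRNOG00000064743 (0.65), ENSRNOG00000062337 (0.87) and ENSRNOG00000068039 (0.51). Mitochondrial genes had a median slope of 0.78, which is partly built in, but AY172581.8, AY172581.6 and AY172581.7, rare genes with a large rise, had 0.12, 0.13 and 0.26 and did not pass. Other rare genes with a large rise passed with low slopes: AY172581.20 with 0.28, AY172581.22 with 0.40, AY172581.21 with 0.46 and AY172581.19 with 0.49. AY172581.2 had 0.59, and the named mRNAs had 0.50 (Mt-atp8) to 0.94 (Mt-nd3). None of 2749 genes without muscle counts rose, and Coch fell with a slope of -0.60 (edgeR adjusted p = 0.00791). The 5 genes could be RNA that purifies with mitochondria or reads shared with the mitochondrial genome. Shared reads as the whole source would leave the ratio to mitochondrial counts as in muscle only if the mitochondrial gene sharing them kept its own ratio. The ratio was higher by 1.69 on the log2 scale for the 5.8S copy and 3.41 for ENSRNOG00000068039. It had values of -0.88 for ENSRNOG00000068307, 0.97 for ENSRNOG00000064743 and 0.14 for ENSRNOG00000062337 (edgeR adjusted p = 0.107, 0.0602 and 0.799). Rare mitochondrial genes themselves rose by 3.49 (AY172581.2) to 8.51 (AY172581.20) relative to mitochondrial counts. Shared reads therefore stay open for all 5 genes.

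Lower depth of the mitochondria libraries could account for the fall of muscle mRNAs, but 54.8% of the nuclear genes that fell still fell after all libraries were thinned to the same nuclear count, or 61.8% of the 6605 tested again. All 36 sarcomere genes tested again fell, with a median log2 fold change of -6.64 against -7.64 before. The values of the 6605 genes moved up by a median of 1.03 (quartiles 0.94 and 1.12), so much of the loss lay in genes with a small fall. Over all genes in both fits the median shift was 0.98, so the whole scale moved and the 54.8% does not measure depth alone. Of the 462 possible splits of the 12 libraries into 6 and 6, 100 were run. Only 1, the real one, called as many genes between mitochondria and muscle (23014, highest other 0). For the transcripts of the mitochondrial genome only 1 of 100, the real one, did so as well (16, highest other 5). Every other split mixed libraries of both groups on each side, so the difference between the groups became spread within the sides. Few calls there were fixed beforehand, and the splits cannot tell how many calls chance would give.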
